A study of Mus musculus with 24 samples.

How the data were processed

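The series measured gene expression in kidney cortex of male mice on the C57BL6/J background, aged 22 months. Lexogen QuantSeq libraries, which tag the 3' end of each transcript, were sequenced as forward reads of 50 bases. Wild type (WT) mice and mice without FGF21 (KO) ate diets with 20% (NP) or 5% (LP) of protein from casein. Per the labels, the diets started at 3 months of age in all groups. This gave 4 groups of 6 libraries, 1 library per mouse, named here WT_NP, WT_LP, KO_NP and KO_LP with a replicate number that is only a name. The labels give no batch, and the index order follows the groups, so a batch that followed the groups could not be separated from them.

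The authors deposited a table of raw counts, in read counts per gene, and a table of normalized values, a signal that equals the counts divided by one size factor per library; every library's ratio of count to normalized value was constant within rounding. Per the labels, the genome build was GRCm38 and DESeq2 1.22.2 was among the tools; the aligner and the counter are not given in the sources used here. Both tables held 16921 genes, and the lowest mean count of a gene was 3, so genes with few counts had been removed upstream. The files gave symbols for 14208 identifiers, GENCODE M21 gave 2668 more together with the coordinates, and 45 identifiers matched neither. Fgf21 and Klb have no row in the tables.

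Raw counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr on the 4 groups were tested (15165 genes, with 1756 below the filter), library factors were TMM, and 1 robust quasi-likelihood fit with 4 group means covered all 24 libraries. The 5 comparisons were LP versus NP in wild type, LP versus NP in KO, the difference of those LP effects (KO minus wild type), and KO versus wild type on each diet. Tests were two-sided with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. Expression in CPM, counts scaled by the library size and its factor, is given as mean ± SD over 6 libraries, and log2 folds come with the standard error (SE) of the fit. Groups of 6 libraries were compared on single values with exact permutation tests, two-sided, and 12 libraries with 12 with a permutation test of 100000 resamples.

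The design, the comparisons, the gene lists, the rule for naming genes and most of the alternatives were fixed before the data were examined. The rule takes, for the diet comparisons, the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM and a proper symbol, and 5 and 5 for the other comparisons. It adds up to 3 members of each list with the smallest p, Fgf21, Klb, Fgfr1 and Kl in every comparison, and, where no gene is called, the 5 genes with the smallest p. Not every gene that the rule takes is described here. Of 43 gene lists (metabolic pathways, stress and immune responses, markers of kidney and other cell types, and neighbours of Fgf21), 41 had at least 5 tested members. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Members were counted as called over all genes tested and again with p adjusted over the list alone. Camera was repeated with the correlation estimated per list, and fry tested whether a list moved on balance in one direction without comparing it with other genes.

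The alternatives fixed beforehand were DESeq2 size factors in place of TMM, no low count filter, a filter of at least 5 CPM in at least 6 libraries, only the 12 compared libraries, limma voom with quality weights, 1 surrogate variable from sva 3.50.0, DESeq2 1.42.0, limma on log2 of the deposited normalized values plus 1, and leaving out each of the 24 libraries in turn. Chosen after seeing the data were fits without WT_NP 1, KO_LP 4 and KO_LP 6, with the mean of immune marker lists as a covariate, with counts thinned to the smallest library, and without genes on chromosome 7. Each count was also set against 100 splits of the same libraries, the real one included. Sequences of genes that were far higher in KO were searched against other genes with blastn 2.17.0. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 prepared tables and figures.

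Totals ran from 8.47 to 21.1 M counts per library (median 15.0). Replicate pairs differed by 5.98 to 69.5 times counting error (chi-square per degree of freedom), with a biological coefficient of variation of 19.6%. Replicates thus differed by more than counting error in every pair. On simulated data of the same depth and spread, with 14997 genes, changes of 2-fold were called in 85.1% of changed genes for diet in wild type, 79.1% for diet in KO and 66.4% for the difference of the LP effects; at 1.5-fold these were 56.7%, 43.3% and 29.9%. Unchanged genes called there numbered 7, 8 and 15. The simulated genes varied independently of each other, without differences between mice that many genes share. These shares can therefore overstate what the real comparisons detect. No library was left out of the main comparisons, and both deposited tables were used.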

Results

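Kidney cortex RNA of 24 mice aged 22 months was profiled after a low protein diet (LP) or a normal protein diet (NP) from 3 months of age. The questions were how LP, against NP, changes gene expression in old age, and what the hormone FGF21 contributes. FGF21 is a hormone that rises in blood when dietary protein is low, and mice without its gene (KO) were compared with wild type mice (WT). Each of the 4 groups held 6 libraries. Totals were 16.5 ± 3.61 M counts (SD, n = 6) in WT_NP, 16.6 ± 1.10 M in WT_LP, 13.6 ± 1.87 M in KO_NP and 12.3 ± 2.06 M in KO_LP. They ran from 8.47 M in KO_LP 1 to 21.1 M in WT_NP 2. On LP the KO totals were lower than the wild type totals (exact permutation p = 0.00216, adjusted p = 0.0173 over 16 tests of library measures). The share of counts from mitochondrially encoded genes was 28.1% ± 1.54 in KO_NP and 23.1% ± 2.66 in KO_LP, a difference of -4.95 points (exact permutation p = 0.00216, adjusted p = 0.0173). In wild type it was 25.3% ± 1.97 on NP and 25.9% ± 1.23 on LP (exact permutation p = 0.623, adjusted p = 0.712).

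The deleted gene itself, Fgf21, and Klb, which encodes its co-receptor, were not analysed here, since neither has a row in the tables. Fgfr1, a receptor for FGF21, stood at 28.9 ± 2.99 CPM in WT_NP, 28.9 ± 2.05 CPM in WT_LP, 28.0 ± 2.87 CPM in KO_NP and 31.9 ± 2.92 CPM in KO_LP. It was not called in any of the 5 comparisons (edgeR quasi-likelihood, adjusted p from 0.136 for LP versus NP in KO, log2 fold 0.19 and above the NP mean in 5 of 6 libraries, to 1.0 for the same contrast in wild type, log2 fold 0.00). Kl, the co-receptor of the related hormone FGF23, was at 139 ± 39.5, 185 ± 60.0, 192 ± 65.0 and 123 ± 35.2 CPM in the same order. It was not called either, with log2 folds on LP of 0.42 in wild type (adjusted p = 1.0) and -0.65 in KO (adjusted p = 0.112), and -1.07 for their difference (SE 0.367, adjusted p = 0.217).

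**Figure D1:**
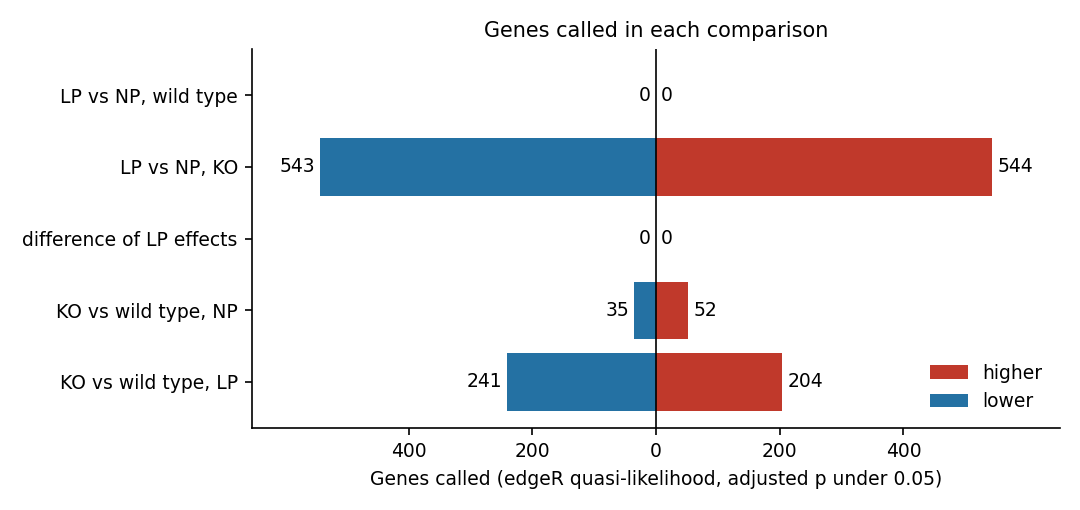
Genes called higher (right) and lower (left) in each of the 5 comparisons, by edgeR quasi-likelihood at an adjusted p under 0.05; the axis counts genes. LP versus NP gave 544 higher and 543 lower genes in KO, 0 in wild type, and 0 for the difference of those effects.

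The first comparison, LP versus NP in wild type, asks what the diet does when FGF21 is present. The 5 genes with the smallest p all missed the threshold. Rarres2, which encodes the adipokine chemerin, was at 90.5 ± 26.2 CPM on LP and 195 ± 39.8 CPM on NP (log2 fold -1.11, SE 0.197, adjusted p = 0.0931, lower in 6 of 6 libraries). S100g, which encodes the calcium carrier calbindin D9k, was at 720.1 ± 228 and 266 ± 79.0 CPM (log2 fold 1.44, SE 0.267, adjusted p = 0.0931, 6 of 6 libraries). The clock repressor Nr1d1 had a log2 fold of -0.43 (SE 0.0811, adjusted p = 0.0931), the desaturase Scd1 one of -1.24 (SE 0.241, adjusted p = 0.118) and the elongase Elovl2 one of 0.89 (SE 0.179, adjusted p = 0.125), each with 6 of 6 libraries on its side. By edgeR quasi-likelihood 0 of 15165 genes were called, with 580 at an unadjusted p under 0.05 where chance alone gives 758. DESeq2 called 16, limma voom with quality weights 6, and limma on the normalized values 0. Without KO_NP 2 edgeR called 2, and without WT_NP 5 it called 1.

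Camera called 9 of 41 lists for LP in wild type, and no member of any list was called over all genes. Markers of the distal convoluted and connecting tubule were higher (10 of 10 members, median log2 fold 0.35, camera adjusted p = 5.1e-07; adjusted p = 0.273 with an estimated correlation, given below as estimated adjusted p). Among them were the calcium genes Calb1 (log2 fold 0.88) and Trpv5 (0.44), and 2 members rose when adjusted over the list alone. The phosphate, vitamin D and calcium list, which shares Calb1 and Trpv5 and holds S100g, was higher too (median log2 fold 0.09, camera adjusted p = 0.00735; estimated adjusted p = 0.273; 3 rose adjusted over the list alone). The NRF2 and glutathione list was lower (20 of 22 members, median log2 fold -0.17, camera adjusted p = 6.0e-07; estimated adjusted p = 0.697). It holds Gsta2 (-1.05), Gstm1 (-0.70) and Abcc4 (-0.80), and 3 members fell adjusted over the list alone. Markers of B and plasma cells were lower (15 of 16 members, median log2 fold -0.78, camera adjusted p = 5.1e-07; estimated adjusted p = 0.724), as Igkc (-1.85). So were those of T and NK cells (median log2 fold -0.51, camera adjusted p = 1.2e-05; estimated adjusted p = 0.831), as Cd3g (-0.82). Macrophage and dendritic cell markers were higher (18 of 19 members, median log2 fold 0.27, camera adjusted p = 0.00142; estimated adjusted p = 0.831). Endothelial markers were higher by a median of 0.09 (adjusted p = 0.0363), immediate early genes lower by -0.31 (adjusted p = 0.0301) and markers of the medulla lower by -0.24 (adjusted p = 0.0355). Their estimated adjusted p were 0.741, 0.831 and 0.831. Outside these lists, Cdkn1c of the podocyte list (log2 fold -0.94), Slc38a3 of the ammoniagenesis list (-1.60), Scd1 of the lipogenesis list and Nr1d1 of the circadian clock list each fell when adjusted over its list alone. By fry 0 of the 41 lists were called. Without WT_NP 1 the camera count was 18, and without WT_LP 5 it was 14. Single libraries also moved the medians. Without WT_NP 1 they were 0.70 for macrophages, -0.086 for T and NK cells and -0.35 for B and plasma cells, and without WT_LP 3 they were -0.94 for T and NK cells and -1.64 for B and plasma cells. The macrophage median was 0.16 without WT_NP 6 and 0.41 without WT_LP 5, and its call ended without WT_NP 4 (0.16), WT_LP 3 (0.16) or WT_LP 4 (0.030). The call of the phosphate list ended without WT_NP 1 (0.081), and its median was 0.15 without WT_NP 4, 0.16 without WT_NP 5, 0.023 without WT_LP 2, 0.17 without WT_LP 3 and 0.15 without WT_LP 4. That of immediate early genes ended without WT_NP 1 (-0.028), WT_NP 6 (-0.25), WT_LP 2 (-0.26) or WT_LP 5 (-0.27). Medulla markers lost theirs without WT_NP 3 (-0.19), WT_NP 6 (-0.26), WT_LP 1 (-0.17) or WT_LP 2 (-0.20). Endothelial markers lost theirs without WT_NP 2 (0.071), WT_NP 4 (0.097), WT_NP 6 (0.078), WT_LP 4 (0.071) or WT_LP 6 (0.062), and were at 0.14 without WT_NP 5.

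The second comparison, LP versus NP in KO, asks what the diet does without FGF21. In KO mice the tubular keratin Krt20 rose from 1.04 ± 0.585 to 7.76 ± 3.14 CPM (log2 fold 2.86, SE 0.642, adjusted p = 0.0228). Amt, an enzyme of glycine breakdown, fell from 69.7 ± 3.18 to 46.1 ± 7.16 CPM (log2 fold -0.60, SE 0.102, adjusted p = 0.00730; chromosome 9, 108296853 to 108302302). The cytochrome oxidase subunit Cox5b fell from 444 ± 35.3 to 338 ± 39.0 CPM (log2 fold -0.39, SE 0.0807, adjusted p = 0.0133). In all, edgeR quasi-likelihood called 544 genes higher and 543 lower of 15165, with 4236 at an unadjusted p under 0.05. Limma on the normalized values called 412 higher and 622 lower, 1034 in all. The count was 183 with 1 surrogate variable, which ended 25 of the 42 named calls, 1693 with voom and 1855 with DESeq2. For each gene named here in the KO diet comparison, all 6 LP libraries lay on the same side of the NP mean, save 5 of 6 for Pdk4, Plin2 and Serpina3n.

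Among the largest rises were Cyp4a14, a fatty acid hydroxylase (log2 fold 3.65, adjusted p = 0.0436), Pdk4, which restrains pyruvate oxidation (3.52, adjusted p = 0.0308), and the injury marker Lcn2 (2.83, adjusted p = 0.0385). Next came the fibrinogen chains Fgg (2.37, adjusted p = 0.0157) and Fga (2.08, adjusted p = 0.0189), the lipid droplet gene Plin2 (2.03, adjusted p = 0.0414) and Serpina3n (2.02, adjusted p = 0.0436). Library KO_LP 6 weighed on most of them. It also had the highest mean log2 CPM of adipocyte markers (5.32, the other KO_LP libraries 3.84 to 4.32) and of 3 adrenal cortex markers (2.62, the others 1.24 to 1.62). Without it the log2 folds were 1.58 for Fgg (adjusted p = 0.0356) and 1.19 for Fga (0.0325), which were still called. They were 1.41 for Cyp4a14 (0.272), 1.06 for Pdk4 (0.215), 1.79 for Lcn2 (0.111) and 0.26 for Plin2 (0.304), which were not. Without KO_NP 2 the Cyp4a14 value was 5.56. Among the largest falls were Alb (-2.20, adjusted p = 0.00932; -1.50 without KO_NP 3, adjusted p = 0.00920), Cox6a2 (-2.03, adjusted p = 0.0104), Car3 (-1.58, adjusted p = 0.0397), the bile acid and steroid reductase Akr1d1 (-1.47, SE 0.209, adjusted p = 0.00382). Smaller ones were Ldc1 (-1.41, adjusted p = 0.0341), the glycogen synthase Gys2 (-1.35, adjusted p = 0.0255) and Ugt2b37 (-1.16, adjusted p = 0.0236). All of these come from edgeR quasi-likelihood with Benjamini-Hochberg adjustment.

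**Figure D2:**
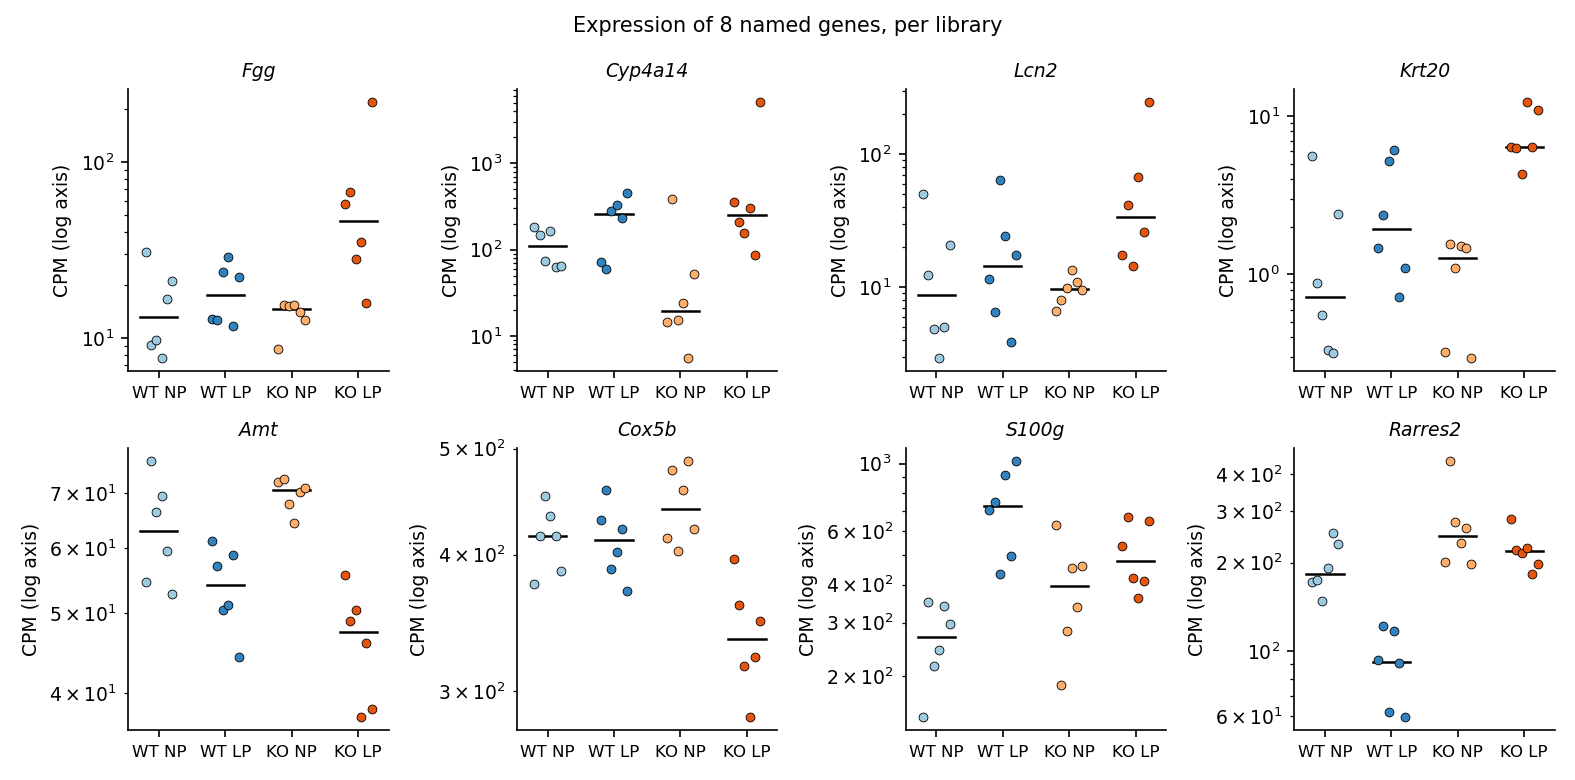
CPM on a log axis of 8 named genes in each library of the 4 groups; points are libraries and bars are group medians. Amt fell by 0.60 and Cox5b fell by 0.39 on the log2 scale from KO_NP to KO_LP, while S100g and Rarres2 were not called in wild type (adjusted p = 0.0931 each).

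Camera with the preset correlation placed lists of mitochondrial and amino acid metabolism lower in KO on LP. Of 71 nuclear genes of oxidative phosphorylation 24 fell and 0 rose over all genes (61 fell adjusted over the list alone), with a median log2 fold of -0.33 (camera adjusted p = 1.1e-26; estimated adjusted p = 0.364). Ndufb7 is an example (-0.34). Of 8 mitochondrially encoded mRNAs 3 fell (6 adjusted over the list alone; median log2 fold -0.50, camera adjusted p = 2.2e-05; estimated adjusted p = 0.364). The mRNA of mt-Nd1 went from 31266 ± 3335 to 21475 ± 3753 CPM, and mt-Co1 had a log2 fold of -0.51. Amino acid catabolism lost 18 of 42 members (32 adjusted over the list alone; median log2 fold -0.41, camera adjusted p = 2.4e-17; estimated adjusted p = 0.364). They include the branched chain enzymes Dbt (-0.70) and Ivd (-0.62) beside Amt. Sterol synthesis fell in 8 of 24 members (12 adjusted over the list alone; median log2 fold -0.31, camera adjusted p = 7.2e-08; estimated adjusted p = 0.364), among them Nsdhl (-0.59) and Mvd (-0.56). The ammoniagenesis and gluconeogenesis list fell by a median of 0.27 (2 of 15 members, 4 adjusted over the list alone, camera adjusted p = 1.7e-04; estimated adjusted p = 0.364), led by the carbonic anhydrase Car2 (-0.67). The urea cycle list fell by a median of 0.22 (2 of 14 members, 2 adjusted over the list alone, camera adjusted p = 0.0156; estimated adjusted p = 0.368), with Gamt (-0.71). Proximal tubule amino acid transporters fell by a median of 0.30 (1 of 18 members, 8 adjusted over the list alone, camera adjusted p = 0.00105; estimated adjusted p = 0.364). By contrast the fatty acid oxidation and PPAR alpha list rose (8 up and 1 down of 32, 13 up and 1 down adjusted over the list alone, median log2 fold 0.40, camera adjusted p = 6.7e-04; estimated adjusted p = 0.541). Without KO_LP 6, the library with the high adipocyte and adrenal cortex markers, this list had a median of 0.14 and was not called (camera adjusted p = 0.0799). Its members include Acot1 (1.85, but 0.68 and adjusted p = 0.0722 without KO_LP 6).

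Camera placed lists of injury, interferon, chemokines and immediate early genes higher, while the unfolded protein response and NRF2 lists given below were not called. The tubular injury list rose by a median of 0.92 (8 of 24 members, 20 up and 1 down adjusted over the list alone, camera adjusted p = 5.9e-08; estimated adjusted p = 0.368). Called members include Krt20, the ferroxidase Cp (log2 fold 1.15) and the repair factor Sox9 (1.60). The interferon list rose by a median of 0.65 (7 of 32 members, 20 adjusted over the list alone, camera adjusted p = 3.5e-08; estimated adjusted p = 0.368), as Irf1 (0.75), Gbp2 (1.03) and Psmb8 (0.97). Chemokines, cytokines and complement rose by a median of 0.91 (4 of 24 members, 9 adjusted over the list alone, camera adjusted p = 4.3e-06; estimated adjusted p = 0.368), with the macrophage growth factor Il34 (1.15). Immediate early genes rose by a median of 0.68 (6 of 16 members, 10 adjusted over the list alone, camera adjusted p = 2.2e-05; estimated adjusted p = 0.368), as Junb (1.03). The ATF4 list rose by a median of 0.44 (3 up and 2 down of 35, 8 up and 2 down adjusted over the list alone, camera adjusted p = 0.0285; estimated adjusted p = 0.461). In it Pck2 (0.50) and Slc38a2 (0.62) rose and Shmt2 (-0.48) fell. The ATF4 call ended without KO_NP 1 (median 0.34) or KO_LP 6 (0.18). Extracellular matrix (median 0.33, adjusted p = 0.0154), cell cycle (0.62, adjusted p = 0.0133) and FGF signalling genes (0.19, adjusted p = 0.0241) had 1, 1 and 0 called members, and 0, 3 and 2 adjusted over the list alone. Their estimated adjusted p were 0.631, 0.578 and 0.364. The matrix call ended without KO_NP 6 (0.30) or KO_LP 4 (0.22), the cell cycle call without KO_LP 4 (0.35) or KO_LP 5 (0.48), and the FGF signalling call without KO_NP 1 (0.17) or KO_LP 6 (0.14). With the immune marker mean as a covariate, chosen after seeing the data, matrix was at -0.11 (camera adjusted p = 0.00141) and cell cycle at -0.26 (camera adjusted p = 0.00382), each called the other way. Of all 25 list calls for LP in KO, that covariate kept 10, ended 12 and reversed 3. Ribosomal protein genes rose by a median of 0.15 (4 of 77 members, as Rps24 at 0.33, and 0 adjusted over the list alone, camera adjusted p = 1.4e-08; estimated adjusted p = 0.422).

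Markers of immune cells moved with these groups and proximal tubule markers moved against them. Macrophage and dendritic cell markers rose by a median of 0.93 (5 of 19 members, 17 adjusted over the list alone, camera adjusted p = 3.9e-07; estimated adjusted p = 0.375), as Cd14 (log2 fold 1.33) and Cd74 (0.99). T and NK cell markers rose by a median of 1.21 (1 of 17 members, Cd3e at 1.27, and 15 adjusted over the list alone, camera adjusted p = 4.3e-06; estimated adjusted p = 0.375). B and plasma cell markers rose by a median of 1.61 (0 of 16 members, 13 adjusted over the list alone, camera adjusted p = 3.1e-04; estimated adjusted p = 0.422), where Tnfrsf17 was at 1.80 (adjusted p = 0.0542). With the immune marker mean, to which these cells belong, as a covariate the B and plasma cell median was -0.14. Proximal tubule S1 and S2 markers fell by a median of 0.35 (2 of 13 members, 5 adjusted over the list alone, camera adjusted p = 2.2e-05; estimated adjusted p = 0.364), as the phosphate carrier Slc34a1 (-0.68). S3 markers fell by a median of 0.43 (1 of 10 members, 2 adjusted over the list alone, camera adjusted p = 0.00456; estimated adjusted p = 0.368). Markers of the thick ascending limb (median -0.21, adjusted p = 0.0403), of the distal convoluted tubule (-0.34, adjusted p = 0.0199) and male-biased kidney genes (-0.44, adjusted p = 0.00527) fell with 0, 0 and 1 called members, and with 0, 0, and 1 up and 3 down adjusted over the list alone. Their estimated adjusted p were 0.461, 0.422 and 0.422. The thick ascending limb call ended without KO_NP 2 (-0.23), KO_NP 3 (-0.24), KO_NP 4 (-0.15), KO_NP 5 (-0.19), KO_LP 2 (-0.19), KO_LP 3 (-0.23) or KO_LP 5 (-0.16). The distal convoluted tubule call ended without KO_LP 6 (-0.20), and the male-biased median was -0.29 without KO_LP 4. Per library, the immune marker mean was 4.05 ± 0.787 log2 CPM on LP and 3.06 ± 0.337 on NP in KO (exact permutation p = 0.0195, adjusted p = 0.0683 over 14 tests). The S1 and S2 mean was 8.35 ± 0.371 and 8.83 ± 0.110 (exact permutation p = 0.00216, adjusted p = 0.0302). In wild type those differences were -0.36 (exact permutation p = 0.405) and 0.03 (exact permutation p = 0.853).

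**Figure D3:**
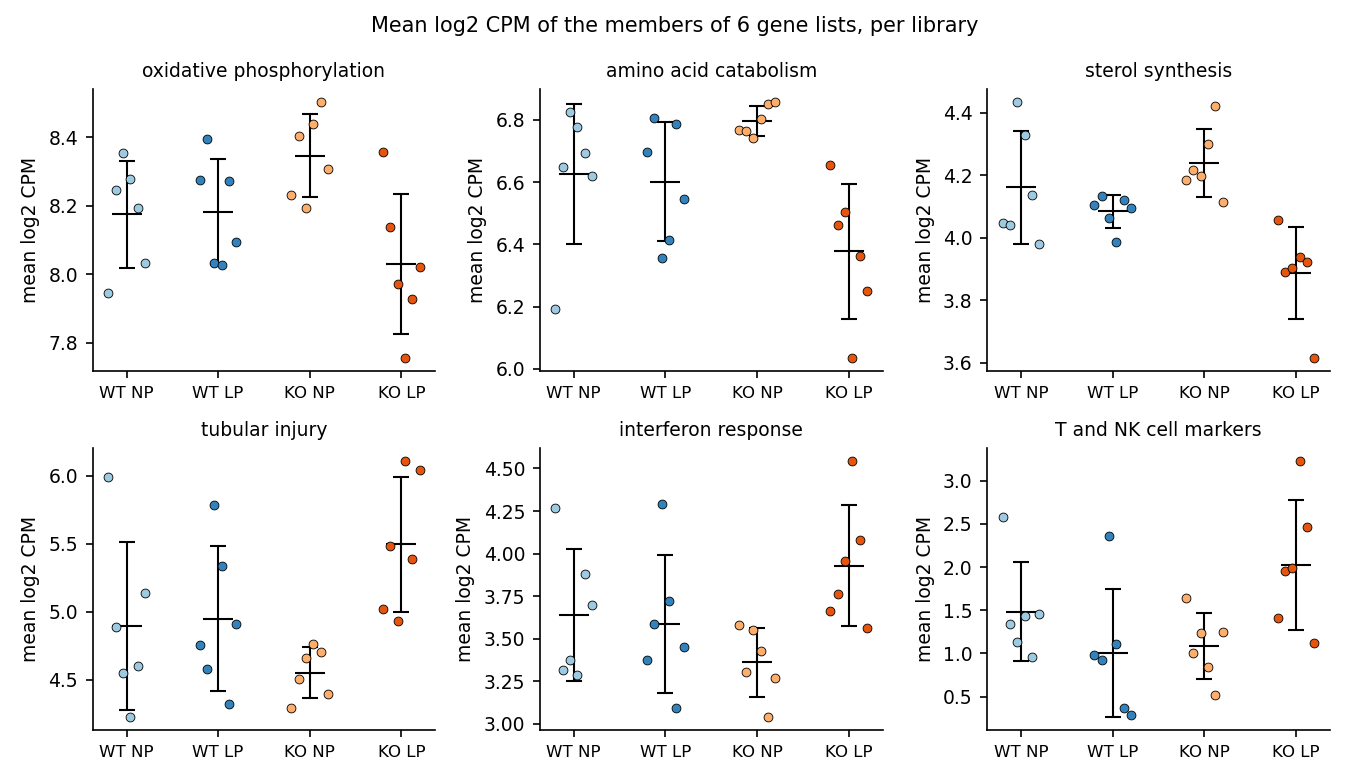
Mean log2 CPM of the members of 6 gene lists in each library; points are libraries, and bars give the mean and SD of 6 libraries. For oxidative phosphorylation the KO_LP mean was 8.03 ± 0.204 and the KO_NP mean 8.35 ± 0.122.

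Of the remaining lists in KO, 16 were tested and not called by camera. Their medians were -0.10 for lipogenesis (1 member fell), -0.04 for the unfolded protein response (1 rose), 0.04 for lysosome and autophagy (1 rose and 1 fell), 0.01 for NRF2 and glutathione (2 fell), 0.69 for senescence (0 called), 0.07 for the circadian clock (1 rose), -0.15 for the renin-angiotensin system (0) and -0.01 for phosphate, vitamin D and calcium handling (1 fell). Among markers they were -0.22 for principal cells (1 fell), -0.17 for intercalated cells (0), -0.13 for the medulla (0), 0.17 for podocytes (1 rose), 0.12 for endothelium (0), -0.33 for red blood cells (0) and 0.41 for adipocytes (1 fell), and 0.11 for neighbours of Fgf21 (1 rose and 3 fell). The lists of neutrophils (4 tested members, 0 called) and adrenal cortex (3 tested, 1 rose) were too short for camera.

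The KO counts depended on single libraries. Without KO_NP 5 the 1087 calls became 122 and without KO_LP 4 136. The count was 399 to 623 without KO_NP 1, 3, 4 or 6 or KO_LP 5 or 6, 2006 without KO_LP 1 and 1759 without WT_NP 1. Of 42 named calls, 12 held in all 24 fits that leave out 1 library: Fgg, Fga, Alb, Cox6a2, Akr1d1, Amt, Dbt, Ivd, Cox5b, Ndufb7, Il34 and Car2. Of the 42, 28 ended without KO_NP 5, 28 without KO_LP 4 and 16 without KO_LP 6, and none changed direction. Without WT_NP 1, KO_LP 4 and KO_LP 6 together, a fit chosen after seeing the data, 36 genes were called. The median log2 fold of the 1087 genes, along their direction, was then 0.43 (median SE 0.138) against 0.56 (median SE 0.145). With the immune marker mean as a covariate, also chosen after seeing the data, 45 were called and that median was 0.38 (median SE 0.147).

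The third comparison tests the difference of the LP effects, KO minus wild type, which is the question in the series title. The genes with the smallest p were Gm26532 (log2 difference 0.92, SE 0.177), Pyurf (-0.49, SE 0.102), Calb1 (-1.38, SE 0.289), Smim20 (-0.42, SE 0.0923) and Akr1d1 (-1.29, SE 0.287), each at adjusted p = 0.158 and with 6 of 6 KO_LP libraries on the side of the KO change. Calb1 stood at 108 ± 35.8 CPM in WT_NP, 199 ± 36.1 in WT_LP, 168 ± 42.0 in KO_NP and 118 ± 26.9 in KO_LP. Cox5b differed by -0.39 (SE 0.114, adjusted p = 0.172), with 6 of 6 libraries. By edgeR quasi-likelihood 0 genes were called, with 2430 at an unadjusted p under 0.05 (758 by chance). DESeq2 called 108 and limma voom 0. The counts of 0 in wild type and 1087 in KO are thus not shown to differ for any gene by edgeR.

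Camera called 24 of 41 lists for the difference, and 0 of 24 with an estimated correlation, where the smallest adjusted p was 0.303. More negative in KO were oxidative phosphorylation (71 of 71 members, median -0.32, adjusted p = 1.0e-23; estimated adjusted p = 0.303). So was the mitochondrially encoded list, with mt-Nd1 at -0.63 (8 of 8 members, median -0.49, adjusted p = 1.3e-05; estimated adjusted p = 0.303). The same held for amino acid catabolism (39 of 42 members, median -0.35, adjusted p = 1.5e-13; estimated adjusted p = 0.303), as Mccc2 (-0.68) and Aadat (-0.98). It held for distal convoluted tubule markers (10 of 10 members, median -0.56, adjusted p = 3.6e-06; estimated adjusted p = 0.303). More positive in KO were tubular injury (23 of 24 members, median 0.999, adjusted p = 6.2e-07; estimated adjusted p = 0.384), as Krt19 (2.57) and with a median of 0.60 without WT_NP 1, and immediate early genes (15 of 16 members, median 0.96, adjusted p = 3.7e-07; estimated adjusted p = 0.303), as Klf4 (1.04). Interferon genes did too (30 of 32 members, median 0.68, adjusted p = 5.9e-08; estimated adjusted p = 0.389). Immune markers moved the same way: T and NK cells (17 of 17 members, median 1.71, adjusted p = 6.7e-10), as Cd3e (1.80), and B and plasma cells (16 of 16 members, median 2.65, adjusted p = 1.8e-08), as Pou2af1 (3.25) and Igkc (3.17), both with estimated adjusted p = 0.303. Adjusted over the list alone, 16 members of amino acid catabolism, 7 mitochondrially encoded mRNAs, 3 distal convoluted tubule markers, 12 immediate early genes, 13 T and NK cell and 14 B and plasma cell markers differed, with 12 up and 1 down in tubular injury and 0 in oxidative phosphorylation and interferon. No member was called over all genes.

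Calls on LP in wild type and in KO shared 0 genes in either direction (Fisher's exact p = 1 each, with 0 calls in wild type), and 1 gene without WT_NP 5. Across the 15165 genes, which are not independent replicates, the log2 folds had a Pearson r of -0.04. Its size and sign depended on single libraries, from -0.23 without WT_LP 3 and -0.16 without WT_NP 4 to 0.31 without WT_NP 1, and it was 0.18 with voom. Of the 1087 genes called in KO, 616 (56.7%) had the same sign in wild type, with a median along the KO direction of 0.02. A score of those genes was 0.000422 ± 0.195 in WT_LP and -0.0406 ± 0.225 in WT_NP (difference 0.0410, exact permutation p = 0.734).

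The fourth comparison, KO versus wild type on NP, shows the genotype without the diet. Klk1b22, a kallikrein of chromosome 7 (44112673 to 44116922), rose from 1.2 ± 0.497 to 76.8 ± 9.15 CPM (log2 fold 6.01, SE 0.290, adjusted p = 2.7e-12). Its reads can be shared with near-identical kallikrein genes, which leaves the value uncertain. Cox6a2 (log2 fold 2.01, adjusted p = 0.00867), Hddc3 (1.99, adjusted p = 1.9e-10), the retinal dehydrogenase Aldh1a1 (1.66, adjusted p = 0.00177) and the branched chain aminotransferase Bcat2 (1.47, adjusted p = 2.0e-06) rose. The glucocorticoid-induced Zbtb16 (-2.25, adjusted p = 0.00363), the protease Pcsk6 (-1.94, adjusted p = 0.00196), Pop4 (-1.34, adjusted p = 4.5e-09), Scd1 (-1.26, adjusted p = 0.00927) and Snord118 (-1.23, adjusted p = 0.0323, 5 of 6 libraries) fell. All others named for NP had 6 of 6 libraries on their side. By edgeR quasi-likelihood 52 genes were higher and 35 lower, with 1915 at an unadjusted p under 0.05. Of these 87, 39 (44.8%) lay on chromosome 7, which holds Fgf21 (45613886 to 45615490) and 7.88% of the tested genes (Fisher's exact p = 1.0e-20, odds ratio 9.79). They started from 24.6 to 128 Mb, and 32 of the 39 started over 5 Mb from Fgf21. With chromosome 7 left out, chosen after seeing the data, 27 genes were called. Over all chromosomes DESeq2 called 232 and voom 140.

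**Figure D4:**
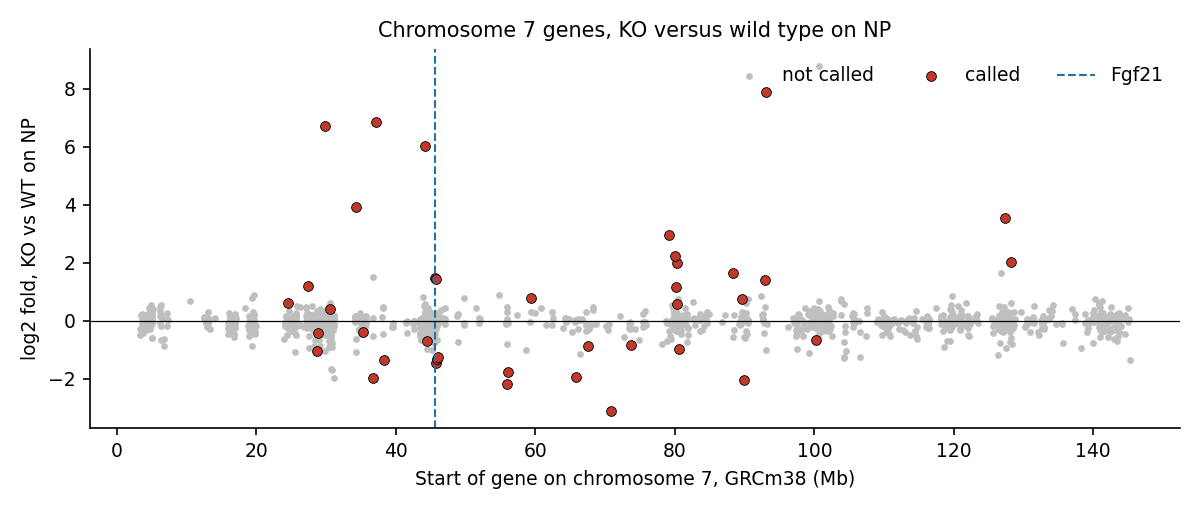
Log2 fold of KO over wild type on NP (vertical axis) against the start of each tested gene on chromosome 7 in Mb, GRCm38; red points are called genes, grey points are not, and the dashed line is Fgf21. The 39 called genes run from 24.6 to 128 Mb.

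Among the lists, neighbours of Fgf21 had 2 up and 2 down of 38 members (3 up and 10 down adjusted over the list alone; camera adjusted p = 0.0756), with Bcat2 and Car11 (1.44) up and Emc10 (-0.70) down. Camera called 21 lists, and 0 with an estimated correlation, where the smallest adjusted p was 0.589. Oxidative phosphorylation rose by a median of 0.16 (1 of 71 members, Cox6b1 at 0.42, and 1 adjusted over the list alone, adjusted p = 2.0e-13; estimated adjusted p = 0.601). Amino acid catabolism rose by 0.18 (1 of 42 members, 2 adjusted over the list alone, adjusted p = 1.3e-05; estimated adjusted p = 0.601). Its 1 called member was Bcat2, the neighbour of Fgf21 named above. Cell type markers moved beside them, proximal tubule S1 and S2 by a median of 0.24, podocytes by -0.41 (-0.26 without WT_NP 1) and endothelium by -0.20. The share of counts from mitochondrially encoded genes was 28.1% in KO_NP and 25.3% in WT_NP (exact permutation p = 0.0173, adjusted p = 0.0554). The unfolded protein response fell by 0.24 (1 of 20 members, Xbp1 at -0.65, and 5 adjusted over the list alone, adjusted p = 7.2e-05; estimated adjusted p = 0.589). Interferon genes fell by a median of 0.36 (1 of 32 members, Bst2 at -1.02, and 1 adjusted over the list alone, adjusted p = 7.5e-04; estimated adjusted p = 0.602). Medulla markers fell by 0.49 (2 of 8 members, Slc5a3 at -0.98 and Cryab at -0.92, and 2 adjusted over the list alone, adjusted p = 0.00240; estimated adjusted p = 0.589). Red blood cell markers rose by a median of 0.88 (0 of 7 members, 3 adjusted over the list alone, adjusted p = 3.0e-04; estimated adjusted p = 0.589). Outside these, Elovl6 (-0.54) and G6pc (-0.75) fell. Of 19 named calls, 12 held in all 24 fits that leave out 1 library, and G6pc, Xbp1, Bst2, Cox6b1, Cryab, Slc5a3 and Snord118 did not. Those that held include Klk1b22, Bcat2, Car11 and Emc10, which lie near Fgf21 on chromosome 7. Without KO_NP 2, 7 of the 19 ended. The count of 87 became 151 without KO_LP 6 and 52 without KO_NP 1, and the 21 lists became 13 without WT_NP 1. Without WT_NP 1 amino acid catabolism was at 0.11 and interferon at -0.16, not called (adjusted p = 0.0629). The unfolded protein response was at -0.097 without WT_NP 3 and red blood cells at 0.40 without KO_NP 2, and the medulla call ended without KO_NP 6 (-0.34).

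The fifth comparison, KO versus wild type on LP, shows the genotype under the diet. Klk1b22 was again high, at 76.6 ± 32.5 against 1.29 ± 0.320 CPM (log2 fold 5.88, SE 0.286, adjusted p = 3.1e-12), with the same doubt about shared reads. Immunoglobulin genes rose: Iglc2 (3.75, adjusted p = 0.0436), Ighg2c (3.26, adjusted p = 0.0237), Iglc1 (2.59, adjusted p = 0.0437) and Jchain (2.38, adjusted p = 0.0342). Reads of the near-identical light chain genes can be shared, and Iglc2 was at 1.21 (adjusted p = 0.305) and Jchain at 1.53 (adjusted p = 0.107) without KO_LP 5, and Iglc1 at 1.64 (adjusted p = 0.119) without KO_LP 2. Pcsk6 (-2.18, adjusted p = 7.3e-04), Snord89 (-1.91, adjusted p = 0.0182), Igf2bp1 (-1.84, adjusted p = 0.0299), the amino acid carrier Slc7a12 (-1.69, adjusted p = 0.0340) and the water channel Aqp4 (-1.59, adjusted p = 0.0444) fell. All genes named for LP had 6 of 6 libraries on their side, save 5 of 6 for Iglc1 and Iglc2. By edgeR quasi-likelihood 204 genes were higher and 241 lower, with 3196 at an unadjusted p under 0.05, and 71 of the 445 (16.0%) lay on chromosome 7 (Fisher's exact p = 9.6e-09). The count was 161 with only the 12 compared libraries, 877 with voom, 889 with DESeq2 and 1958 with 1 surrogate variable.

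Camera called 19 lists on LP, and 0 with an estimated correlation, where the smallest adjusted p was 0.531. B and plasma cell markers rose by a median of 1.64 (5 of 16 members, 10 adjusted over the list alone, adjusted p = 4.8e-07; estimated adjusted p = 0.531), among them Tnfrsf17 (2.60; 1.93 and adjusted p = 0.0607 without KO_LP 5). T and NK cell markers rose by 1.11 (1 of 17 members, Gzmk at 1.64, or 2.26 without WT_LP 3, with a list median of 0.71 without KO_LP 4, and 13 adjusted over the list alone, adjusted p = 5.0e-08; estimated adjusted p = 0.531). Amino acid catabolism fell by a median of 0.19 (1 up and 4 down of 42, 1 up and 11 down adjusted over the list alone, adjusted p = 2.4e-06; estimated adjusted p = 0.531), with Mccc2 (-0.68) and Aadat (-0.90) down and Bcat2 (0.75) up. With the immune marker mean as a covariate, chosen after seeing the data, this list was at 0.015 and not called (camera adjusted p = 0.790). Distal convoluted tubule markers fell by a median of 0.52 (2 of 10 members, Klk1 at -1.18 and Calb1 at -0.74, and 2 adjusted over the list alone, adjusted p = 2.3e-04; estimated adjusted p = 0.531). Klk1 shares sequence with Klk1b22 and is uncertain. Endothelial markers fell by 0.21 (1 of 14 members, Eng at -0.42, and 6 adjusted over the list alone, adjusted p = 4.7e-04; estimated adjusted p = 0.531). Sterol synthesis fell by 0.17 (2 of 24 members, among them Sc5d at -0.72, and 2 adjusted over the list alone, adjusted p = 6.5e-04; estimated adjusted p = 0.531). In other lists Slc22a13 (-1.05), Slc7a7 (-0.60), Kcnj1 (-0.47), Oat (-0.36) and Rplp1 (-0.57, uncertain because a near-identical copy can take its reads) fell, and Il34 (1.01), Slc20a1 (0.69) and Bhlhe40 (0.42) rose. Near Fgf21, Car11 (1.44) was up and Emc10 (-0.75) and Josd2 (-0.67) were down. Of 30 named calls, 12 held in all 24 fits that leave out 1 library, while 14 ended without WT_LP 1, 14 without WT_LP 6 and 12 without KO_LP 4. The count of 445 became 180 without WT_LP 1, 208 without KO_LP 4, 233, 268 and 263 without WT_LP 2, 5 and 6, 733 without WT_LP 3 and 708 without WT_NP 1.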

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

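The tests of explanations in this part, the splits among them, were chosen or had their bounds set only after the results were seen, as were the fits without WT_NP 1, KO_LP 4 and KO_LP 6, with the immune marker mean, with thinned counts and without chromosome 7. The search for libraries that stand apart and the test of the difference of the LP effects were planned.

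In 42 of 451 groups of 6 libraries (9.31%), 1 library lay far from the other 5 by Dixon's gap test. Chance gives about 1 in 20 groups, and the genes and lists are not independent of each other. KO_LP 6 lay apart in the log2 CPM of Cyp4a14 (12.33), Pdk4 (7.16), Plin2 (10.36), Gys2 (-1.17), Ugt2b37 (7.31), Nsdhl (4.12), Il34 (7.63), Gamt (2.59) and Slc20a1 (6.31). It also lay apart in the mean log2 CPM of ATF4 targets (4.65), NRF2 and glutathione genes (7.14), distal convoluted tubule markers (4.11) and adipocyte markers (5.32). Its score on principal component PC3 was -46.6. WT_NP 1 lay apart in Cx3cr1 (5.97), Pyurf (4.93), Aadat (5.74) and Klk1b22 (-1.34). It did so in the means of amino acid catabolism (6.19), chemokines (4.64), cell cycle (2.98), intercalated cells (3.11), macrophages (6.84) and T and NK cells (2.58). Its score on principal component PC1 was -38.4. KO_LP 4 lay apart in Irf1 (6.47) and Gbp2 (5.02), and KO_LP 5 in Jchain (10.08) and Iglc2 (9.53). KO_LP 1 did so in Aqp4 (4.34) and in its total of 8.47 M counts. KO_NP 1 did so in Fgg (3.15), Pck2 (2.84) and Gm26532 (2.61). KO_NP 2 did so in Emc10 (6.31) and red blood cell markers (7.44), and KO_NP 6 in Hddc3 (4.23). The others were WT_NP 3 in medulla markers (4.67), WT_NP 4 in Xbp1 (6.64), WT_LP 3 in ATF4 targets (4.46), WT_LP 4 in Oat (6.39) and WT_LP 5 in amino acid transporters (6.32).

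The LP effect differed between genotypes, by camera with the preset correlation, in 24 lists, given here as the median log2 fold, KO minus wild type. With an estimated correlation 0 of the 24 were called, and with fry 0. The effect was more positive in KO for ATF4 targets (0.27), fatty acid oxidation (0.43), ribosomal proteins (0.14), extracellular matrix (0.38), tubular injury (0.999), chemokines (0.67), interferon (0.68) and immediate early genes (0.96). The same held for markers of podocytes (0.34), macrophages (0.73), T and NK cells (1.71) and B and plasma cells (2.65). It was more negative for amino acid catabolism (-0.35), urea cycle (-0.30), ammoniagenesis (-0.29), amino acid transporters (-0.33), sterol synthesis (-0.26), oxidative phosphorylation (-0.32), mitochondrially encoded mRNAs (-0.49), and phosphate and calcium handling (-0.27). Markers of proximal tubule S1 and S2 (-0.33), S3 (-0.30), distal convoluted tubule (-0.56) and intercalated cells (-0.31) were more negative too. Of the 24 calls, 15 were kept in every fit that leaves out 1 library and 9 ended in at least 1. Those of ATF4 targets (in 15 of 24 fits), S3 (12), podocytes (11) and intercalated cells (8) ended most often. Their medians went to 0.13 without KO_LP 6, -0.21 without KO_LP 6, 0.17 without WT_NP 1 and -0.24 without WT_NP 1, and ATF4 targets to 0.44 without WT_LP 3. Without WT_NP 1 the calls of extracellular matrix (0.083), macrophages (0.30), ammoniagenesis (-0.19) and phosphate handling (-0.20) ended. That of matrix also ended without WT_LP 5 (0.27), KO_NP 6 (0.34) or KO_LP 4 (0.20), that of macrophages without KO_LP 4 (0.41) and that of ammoniagenesis without WT_NP 5 (-0.27). The fatty acid oxidation call ended without KO_LP 6 (0.14) or KO_LP 1 (0.38). Medians moved with the call kept for tubular injury (0.60) and chemokines (0.30) without WT_NP 1, ribosomal proteins without KO_NP 3 (0.092), urea cycle without KO_LP 6 (-0.19) and phosphate handling without WT_NP 2 (-0.17). The immune marker mean as a covariate, chosen after seeing the data, kept 6 of the 24 calls. With it the direction turned for extracellular matrix (-0.32), chemokines (-0.17), podocytes (-0.16) and macrophages (-0.40). Macrophage markers are part of that mean, so their own turn is not a separate result.

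The KO versus wild type calls on NP gathered on chromosome 7, with 44.8% of the calls there against 7.88% of the tested genes. The tables argue against an effect of the deletion on adjacent genes as the whole cause, since 32 of the 39 calls start over 5 Mb from Fgf21. Loss of the FGF21 signal would have no evident reason to favour this chromosome. That is an assumption, since Fisher's exact test (p = 1.0e-20) shows only the excess itself. DNA of another strain kept around the deleted locus is a candidate explanation that calls from 24.6 to 128 Mb would allow, and no strain variant was read here. For the 27 genes called with chromosome 7 left out, the 3 copies below among them, an effect of FGF21 stays open, apart from what is given below for Gm15459 and Gm11942. Beyond those copies it was not tested.

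Copies of other genes, chosen after their values were seen, were far higher in KO on both diets. They were Gm15459 (log2 fold 9.58 on NP and 10.68 on LP), Gm11942 (8.89 and 9.93) and Gm9008 (4.42 and 3.66), from wild type values of at most 2.90 CPM, so that these folds depend on the prior count. By the count of KO values within the wild type range, loss of FGF21 as the direct cause cannot be told apart from other sources. Such values were 4 of the 36, although every KO mouse lacks Fgf21. They come from 2 of 12 mice, 3 from KO_NP 6 and 1 from KO_NP 4. Within KO, Gm15459 was highest in KO_NP 2, KO_NP 5 and KO_LP 2 (116, 143 and 134 CPM). There Hspa8, its nearest gene, was lowest (69.6, 95.1 and 74.6 CPM). KO_NP 6 had the lowest Gm15459 (0.0988 CPM) and the highest Hspa8 (438 CPM). Gm11942 was within the wild type range in KO_NP 4 and KO_NP 6 (1.42 and 1.68 CPM), where Rplp1, its nearest gene, was highest within KO (1025 and 1041 CPM). Gm11942 was highest in KO_LP 2 (1612 CPM), where Rplp1 was lowest (575 CPM). In KO_NP 2, by contrast, both were high (740 and 906 CPM). Loss of FGF21 is shared by these mice, so these values argue against it alone as the cause for Gm15459 and Gm11942. All 3 copies have their nearest other gene on chromosome 9 (Hspa8 at 99.7% identity, Rplp1 at 97.4%, Rnf26 at 99.1%, one-sided binomial p = 1.7e-04), and these genes were lower in KO by a mean of -0.83 log2 CPM (permutation p = 2e-05). Reads of variant source genes on chromosome 9 may therefore have been assigned to their copies, which leaves Rplp1, Hspa8 and Rnf26 uncertain as expression changes.

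LP gave 1087 calls in KO and 0 in wild type by edgeR (580 there at an unadjusted p under 0.05, 16 called by DESeq2 and 6 by voom). Chance is unlikely for the first, where the highest of the other splits had 393. A difference in depth is argued against as the whole cause, since 639 genes were called with every library thinned to one depth. Mean totals were lower in KO (13.6 M on NP and 12.3 M on LP) than in wild type (16.5 M and 16.6 M). Lower depth would not favour more calls in KO. A lower share of proximal tubule in the tissue pieces stays open. Immune markers parted by 1.10 log2 CPM from podocyte, endothelial and distal markers, which such a loss would raise alike (exact permutation p = 0.0108, adjusted p = 0.0504 over 14 tests, so it misses the correction). A rise of immune cells would part them whether or not that share also fell. S1 and S2 markers changed by -0.48 (exact permutation p = 0.00216, adjusted p = 0.0302). Distal nephron markers changed by -0.25 (exact permutation p = 0.0368, adjusted p = 0.0859). A few libraries that stand apart cannot be told apart from the diet as the source of the count, since 36 genes were called without WT_NP 1, KO_LP 4 and KO_LP 6 while the median log2 fold went from 0.56 (median SE 0.145) to 0.43 (0.138). Fewer libraries can by themselves lower a count. Without WT_NP 1 alone the count rose to 1759, with the median log2 fold at 0.56 (median SE 0.139). That library is in neither KO group and acts only through what the fit shares over all groups. Its removal therefore says nothing on the effect of fewer KO libraries. An immune response may be part of the diet effect or a state of some mice, since the immune covariate left 45 calls as the median went to 0.38 (median SE 0.147), and an effect of LP that FGF21 restrains stays open, with 0 genes called for the difference by edgeR and 108 by DESeq2.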

How the results depend on the processing

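The fits without WT_NP 1, KO_LP 4 and KO_LP 6 (below: without 3 libraries), with the immune marker mean as covariate, with thinned counts and without chromosome 7 were chosen after seeing the data. The other alternatives here were planned. Where no cause is named, the cause was not tested. No paired analysis was possible because the labels give animal tags that no 2 groups share. DESeq2 size factors, no low count filter and the stricter filter kept every count of genes and lists within 1.5 times. Calls for LP in wild type (0) were 6 with voom, 16 with DESeq2 and 3 with the immune covariate, and 0 to 2 (without KO_NP 2) leaving out 1 library. LP calls in KO (1087) were 1693 with voom, 183 with the surrogate variable, 1855 with DESeq2, 36 without 3 libraries (fewer samples may be part of this), 45 with the immune covariate and 639 with thinned counts (fewer counts). Leaving out 1 library they were 122 (without KO_NP 5) to 2006 (without KO_LP 1). Calls for the difference (0) were 108 with DESeq2 and 0 to 0 leaving out 1 library. KO versus wild type on NP (87) gave 140 with voom, 232 with DESeq2 and 40 thinned. It gave 27 without chromosome 7, where 39 of the 87 lay, so the loss of those genes is only part of that drop. With 1 library left out it gave 52 (without KO_NP 1) to 151 (without KO_LP 6). On LP (445) it gave 161 with only the 12 compared libraries, 877 with voom, 1958 with the surrogate variable, 889 with DESeq2, 200 without 3 libraries, 205 with the immune covariate and 259 thinned. Leaving out 1 library it gave 180 (without WT_LP 1) to 733 (without WT_LP 3). The overlap of the LP calls (0) was 2 with voom and 5 with DESeq2, and 0 to 1 (without WT_NP 5) leaving out 1 library. List calls became 0 in all 5 comparisons with an estimated correlation. With fry they were 0 for LP in wild type (9 by camera), 15 for LP in KO (25), 0 for the difference (24), 0 on NP (21) and 1 on LP (19). With the immune covariate they were 17 for LP in wild type and 12 each for LP in KO, the difference and KO versus wild type on LP. Such totals include gained and reversed lists. For LP in KO 10 of the 25 main calls were kept and 12 lost, and for the difference 6 of 24 were kept and 14 lost. Without 3 libraries they were 18 for LP in wild type and 14 for the difference, with voom 17 for LP in wild type, and with the surrogate variable 12 on NP. Leaving out 1 library they were 7 (without WT_NP 6) to 18 (without WT_NP 1) for LP in wild type, 23 to 26 for LP in KO, 16 to 25 for the difference, 13 (without WT_NP 1) to 24 on NP and 17 to 21 on LP. The direction that camera gives reversed in some lists, given with their median log2 fold. For LP in wild type oxidative phosphorylation, up by camera at a median of -0.0018, was -0.037 without 3 libraries and -0.058 with the immune covariate, and -0.042 to 0.038 leaving out 1 library (reversed without WT_NP 1, -0.039). Extracellular matrix was 0.13 and 0.10 there, and -0.20 to 0.13 leaving out 1 library (reversed without WT_NP 1), and interferon 0.14 with the immune covariate. B and plasma cell and macrophage markers are part of the immune covariate, so their own turns with it are not separate results. The next reversals came with that covariate, which removes what moves with immune markers. For LP in KO they were extracellular matrix (-0.11), cell cycle (-0.26) and B and plasma cells (-0.14). For the difference they were extracellular matrix (-0.32, and -0.040 without 3 libraries), chemokines (-0.17), cell cycle (-0.47), podocytes (-0.16) and macrophages (-0.40). On LP they were amino acid catabolism (0.015), oxidative phosphorylation (0.026), extracellular matrix (-0.19), chemokines (-0.055), interferon (-0.079), cell cycle (-0.45) and macrophages (-0.35). With the surrogate variable on NP they were extracellular matrix (0.16), chemokines (0.19), macrophages (0.46), T and NK cells (0.0030) and B and plasma cells (0.019). Of the named genes that were called in either fit, 0 reversed under these alternatives. Lists and genes called in neither fit were not counted as reversed. Depth limits how many genes are called, as the thinned counts show, although replicate pairs differed by at least 5.98 times counting error.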

Other observations

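The tests by other splits of the libraries and of chromosome 9 in this part were chosen or had their bounds set only after the results were seen, and the list tests were planned.

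Markers of kidney cell types and 2 other lists also differed between genotypes by camera with the preset correlation, but not with an estimated one (adjusted p = 0.589 to 0.601 on NP and 0.531 on LP). By fry the adjusted p was 0.116 to 0.327 on NP and 0.193 to 0.225 on LP, so neither called them. On NP, proximal tubule S1 and S2 markers were higher in KO by a median log2 fold of 0.24 (11 of 13 members, adjusted p = 6.9e-04) and male-biased kidney genes by 0.33 (13 of 15 members, adjusted p = 0.00469). Podocyte markers were lower by a median of -0.41 (10 of 12 members, adjusted p = 7.5e-04) and endothelial markers by -0.20 (13 of 14 members, adjusted p = 0.00103). On LP, unfolded protein response genes were lower in KO by a median of -0.16 (19 of 20 members, adjusted p = 0.00302). Thick ascending limb markers were lower there by -0.34 (7 of 10 members, adjusted p = 0.0115) and proximal tubule S3 markers by -0.22 (7 of 10 members, adjusted p = 0.0313). Without WT_NP 1 the podocyte median on NP was -0.26. On LP the unfolded protein response call ended without WT_LP 2 (-0.11) and the thick ascending limb call without KO_LP 2 (-0.29). The S3 call ended without WT_LP 5 (-0.17), KO_LP 2 (-0.21), KO_LP 4 (-0.15) or KO_LP 6 (-0.097), and its median was -0.079 without WT_LP 2 and -0.33 without WT_LP 4. Chromosome 9 held 11 of the 87 calls on NP (12.6%) and 38 of the 445 on LP (8.54%), against 5.51% of the tested genes (Fisher's exact p = 0.00813 and 0.00794). It also held 77 of the 1087 calls for LP versus NP within KO (7.08%, Fisher's exact p = 0.0226). KO mice differed from each other in Gm11942, whose nearest gene lies on chromosome 9 (1.42 CPM in KO_NP 4, 1612 CPM in KO_LP 2). Whether the excess within KO is separate from genotype therefore cannot be told.

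Each count was compared with 100 splits of the same libraries into groups of the same sizes, the real one included. For the difference of the LP effects, the splits exchanged genotype labels within each diet. They thus mix genotype effects into the difference and its spread, so their shares do not measure chance for the difference alone. Chance is unlikely for the 1087 LP calls in KO (1 of 100 splits gave as many, highest other 393), the 87 calls on NP (1 of 100, highest other 9) and the 445 on LP (1 of 100, highest other 1). A share of 1 in 100 is the smallest that these splits can give, and it was not corrected for the number of such tests. A count of 0 is reached by every split, so this comparison says nothing on chance for the counts of 0 by edgeR for LP in wild type (100 of 100, highest other 5) and for the difference of the LP effects (100 of 100, highest other 50). In the latter, 3 of 100 splits gave any call, and whether the 50 calls of 1 split reflect a structure of the samples was not tested. At an unadjusted p under 0.05 the real counts there were 580, which 48 of 100 splits reached (highest other 2479), and 2430, which 2 of 100 reached (highest other 2605). DESeq2 called 16 and 108. For lists at the preset correlation, few splits reached the 25 called for LP in KO (2 of 100, highest other 26) and the 24 called for the difference (4 of 100, highest other 26). Other splits called more lists than either, the shares were not corrected for the number of such tests, and with an estimated correlation 0 of either were called, so whether chance can be excluded for them stays open. It cannot be excluded for the 9 called for LP in wild type (81 of 100, highest other 24), the 21 on NP (12 of 100, highest other 24) or the 19 on LP (30 of 100, highest other 26). The other splits called a median of 12 to 15 lists, so many list calls at the preset correlation arise from splits that follow no group.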
